A study of Mus musculus with 4 samples.

How the data were processed

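Total RNA of mouse bone marrow-derived dendritic cells was depleted of ribosomal RNA and made into stranded Illumina libraries from 1 ug, per the labels' protocols. The 4 groups (control medium, Wnt2, CAF.CM, CAF.CM + Wnt2 antibody) have 1 column each, taken from the treatment label and treated as 1 library, though pooling of several is not excluded by the sources used here. STAR 2.4.2a, RSEM 1.2.29 and edgeR, with builds GRCm38.p5 and mm10, are named in the submitters' processing notes. Their settings, their order and whether counting used strand are not given in the sources used here.

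The deposited library columns hold normalized CPM, not log transformed, with 3 decimals, in 1 table per comparison. Their column sums differ between libraries, as after scaling of library sizes. The authors also deposited log2 fold changes and log2 mean CPM, per the file headers. P-values and adjusted p-values are the authors' deposited values, and the dispersion behind them is not stated. The libraries present in 2 tables had identical values in both, for 12954 of 12954 genes for control medium and 12848 of 12848 for CAF.CM. Each table lists only genes that reached about 1 CPM in at least 1 of its libraries, so a gene missing from a table is not shown to be unexpressed. Some genes may also have been left out of the material used here.

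The plan had assumed expected counts, while the files hold CPM. Nearly all CPM values were found to be whole multiples of 1 step per library, which is what 1 read is worth. Within a tolerance of 0.1 step, 99.96% of control, 99.99% of Wnt2 and 100% of CAF.CM and antibody values were whole, and the reads were recovered from these steps. The fit was tested on simulated data and returned the exact count for 100% of genes. A count test with p-values was not run, since 1 library per group leaves no estimate of the spread. A read was worth 0.00706 CPM in control medium, 0.00651 in Wnt2, 0.0384 in CAF.CM and 0.0431 in the antibody library, so precision is lower in the last 2.

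Log2 ratios were computed with edgeR 4.0.16 in R 4.3.3 as log2 CPM with a prior count of 2 and the authors' effective library sizes. Exact conditional binomial intervals at 95% were computed with scipy 1.17.1 in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The planned filter of 10 counts and 1 CPM removed no gene. On simulated libraries 100% of 4-fold genes were called in each comparison, and 0 of 12920, 8 of 13129 and 8 of 12872 unchanged genes passed 2-fold for Wnt2, CAF.CM and antibody. Other simulations of unchanged libraries assumed a biological coefficient of variation of 0.2, over 12954 genes. They gave on average 113 higher and 110 lower genes for Wnt2, and 125 and 161 for CAF.CM. Such numbers are not given here for the antibody comparison. The number of unchanged genes that pass 2-fold thus depends on the spread assumed.

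The comparisons, 35 gene lists (12 of them markers of cell types), the rule for named genes and the first set of alternatives were fixed before the data were examined. Named genes are the 12 highest and 12 lowest protein-coding genes per comparison with at least 200 counts over both libraries and 5 CPM in 1, leaving out predicted, unnamed and mitochondrial genes. Up to 4 members per list with the largest ratio, 13 genes fixed in advance, and up to 8 genes per direction for the reversal were added. Some genes that the rule took are not reported here. A gene that the rule took in 1 comparison may be given in the others too. Rn7s1, Rn7s2, Lyz2, Cd68, Csf1r, Ccl9, Ccl3, Tnf, Chil3, Ccl24, Ccl22, Clec10a, Pfkfb4, Ly6c2, Fcgr3, Scd1, Scd2, Npc2, Timp2 and Malat1 fall outside the rule and were chosen after their values were seen. Where 2 identifiers carry 1 symbol, lists use the one with more reads, a step added after the values were seen. List medians were set against 10000 random lists of the same size matched on expression. Comparisons of comparisons used 20 simulated sets per setting at assumed biological coefficients of variation of 0, 0.1 and 0.2.

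Alternatives were DESeq2 1.42.0 size factors, total counts, a minimum of 100 counts, prior counts of 0.5 and 5, protein-coding genes only, the deposited log2 fold changes, a 1.5-fold threshold, Spearman correlation, and thinning of a shared library into 2 separate parts. Own TMM factors and thinning of the deeper library were added after seeing the data. Gene positions and transcript sequences came from GENCODE M21, which matched 99.86%, 99.83% and 99.84% of listed genes. Shared sequence is the percentage of 31-base words of a gene's longest transcript found in another gene's longest transcript.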

Results

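RNA-seq of mouse bone marrow-derived dendritic cells was analysed in 4 groups with 1 column of values each. The cells came from C57BL/6 mice aged 4 weeks and were grown for 7 days with 10 ng/ml IL-4 and 10 ng/ml GM-CSF. They were kept in control medium, given the secreted ligand Wnt2, given the culture medium of CAFs (CAF.CM; CAF is the usual abbreviation for cancer-associated fibroblast), or given CAF.CM that had first been incubated with an antibody to Wnt2. The tables held 143071376 reads in listed genes for control medium, 154399767 for Wnt2, 25225220 for CAF.CM and 22791494 for CAF.CM + Wnt2 antibody. The series text speaks of triplicates, and whether a column is 1 library or pools several is not given in the sources used here. Each column is called a library below and has no replicate beside it, so no difference below has a replicate check and none carries a p-value. Intervals of single genes are 95% exact binomial intervals on the ratio of 2 libraries and cover counting error only. Those of medians and spreads in the closing section come from redrawing counts at random (counting intervals) or from resampling genes (bootstrap intervals). Genes are not replicates, so bootstrap intervals do not show the spread between cultures. Ratios are log2 unless a fold is named, and a gene is called higher or lower where it differed at least 2-fold.

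The first comparison asks which genes Wnt2 targets in dendritic cells, as the series title puts it. MHC class II presentation genes were lower with Wnt2 than in control medium. H2-Eb1, an MHC class II beta chain, was 12.7-fold lower (log2 ratio -3.66, interval -3.71 to -3.62), and H2-Aa, H2-Ab1 and the invariant chain gene Cd74 stood at -3.31, -2.78 and -3.14. Ciita, the master transactivator of MHC class II genes, was at -2.84 (interval -2.97 to -2.73). Of 12 measured members 7 were lower and 0 higher, and the list median of -1.39 lay at percentile 0 of 10000 random lists matched on expression, as a description of these libraries. Other lists were as extreme with Wnt2. Interferon-stimulated and integrated stress genes also lay at percentile 0, and inflammatory and glycolysis genes at 100. MHC class I genes had 0 of 16 members beyond 2-fold, with a median of -0.25, which lay at percentile 1.18.

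Among all named genes the lowest with Wnt2 was Cd5l, a macrophage-secreted scavenger protein gene, at 51.9-fold lower (log2 ratio -5.70, interval -6.00 to -5.46). Clec12a (-5.19), Marco (-4.01), the lipoprotein lipase gene Lpl (-3.85), Ptx3 (-3.79), Cx3cr1 (-3.48), Clec4b1 (-3.41), Mamdc2 (-3.18) and Chn2 (-3.05) followed. Lpl went from 4096 CPM in control medium to 283.4 CPM with Wnt2. The highest was Lepr, the leptin receptor gene, at 29.6-fold higher (log2 ratio 4.89, interval 4.65 to 5.18). Ackr3 (4.60), Ifitm1 (3.99), Vcan (3.99), Ddit4 (3.88), Serpinb2 (3.51), Smpd5 (3.44), Ptgs2 (3.37), Dgat2 (3.33), Nt5e (3.33), Trem1 (3.29) and Tnfrsf9 (3.09) were also higher. Thbs1, which encodes thrombospondin-1, was among the most abundant transcripts and went from 8256 to 37682 CPM.

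Inflammatory cytokine and chemokine genes were higher with Wnt2 in 9 of 23 measured members and lower in 1, with a median of 0.66. The prostaglandin synthase gene Ptgs2 (3.37), Cxcl3 (2.67), Lif (2.31) and Il1b (2.30) led them. Interferon-stimulated genes went the other way, with 6 of 28 lower, 0 higher and a median of -0.32. Ifit3 (-1.80), Cmpk2 (-1.43), Ifit2 (-1.25) and Ifit1 (-1.10) were the lowest of these. Glycolysis and hypoxia genes had a median of 0.52 with 4 of 27 higher, among them Egln3 (1.99) and Pfkfb3 (1.04). Matrix and adhesion genes were higher with Wnt2 in 8 of 24 members, among them Vcan (3.99), Serpinb2 (3.51) and Thbs1 (2.19), and lower in 2, Timp2 (-1.24) and Mmp12 (-1.03), with a median of 0.11. Genes of the integrated stress response had a median of -0.47, with 3 of 20 lower, among them Atf3 (-2.01) and Psat1 (-1.81), and 1 higher, Ddit4.

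Dendritic cell maturation and costimulation genes were higher in 2 of 19 members, with Tnfsf9 at 1.48 and the costimulatory ligand gene Cd86 at 2.30-fold higher (81.2 against 35.2 CPM). Cd80 was at 0.99, Cd40 at -0.35 and Cd274, which encodes PD-L1, at 0.67. The conventional dendritic cell list had 2 of 17 members lower, Itgax (-1.99) and Batf3 (-1.43), with Itgax, the CD11c gene, going from 887.6 to 222.8 CPM. Socs3, a feedback inhibitor of JAK-STAT signalling, was 2.92-fold higher (log2 ratio 1.54, interval 1.47 to 1.62), while Stat3 (0.22) and Jak2 (0.11) lay within 2-fold. Of the canonical Wnt target list, 11 of 20 genes, Axin2 included, were listed in no table. Of the 9 measured, Sox4 (2.19) and Apcdd1 (1.60) were higher and Ccnd1 (-1.63) and Myc (-1.22) lower. Ctnnb1, the beta-catenin gene, stood at 0.05. Macrophage and monocyte markers were lower in 5 of 18 members, led by C1qc (-2.10), and higher in 2, Vcan (3.99) and Cd14 (1.15). Neutrophil markers were higher in 4 of 5 measured members, with Mmp8 at 1.45, while 11 of the 16 were listed in no table.

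Across all 13120 listed genes, 376 were higher and 385 lower with Wnt2, and for 289 and 276 of them the counting interval lay wholly beyond 2-fold. Of all genes in the authors' deposited table, 2014 had an adjusted p below 0.05, 965 of them higher and 1049 lower. How those p-values were obtained from 1 library per group is not given in the sources used here.

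**Figure D1:**
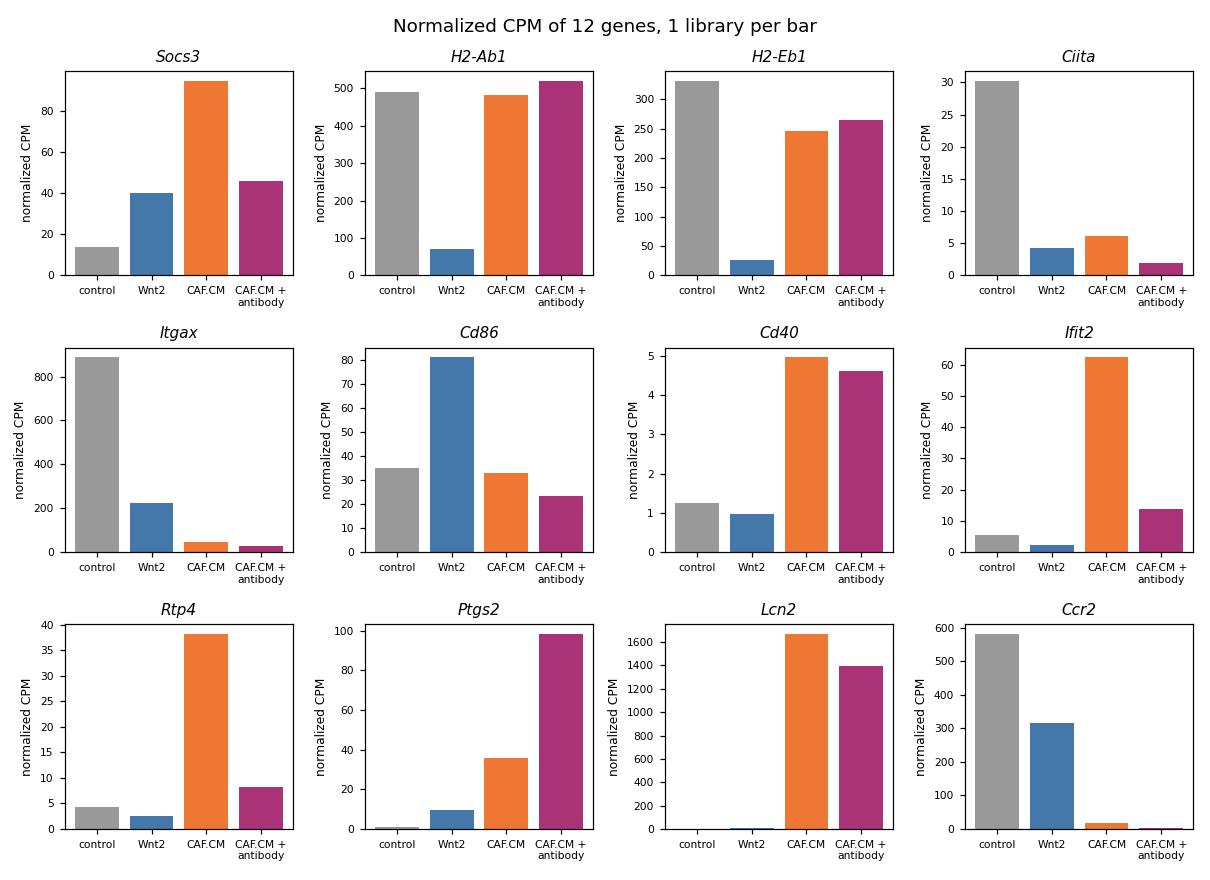
Normalized CPM (linear axes from 0) of 12 genes in the 4 libraries, 1 bar per library and no error bar because each group has 1 library. H2-Ab1 was 489.3 CPM in control medium and 71.0 CPM with Wnt2 against 483.2 CPM with CAF.CM, and Socs3 was 13.8, 40.2, 94.9 and 45.9 CPM in control medium, Wnt2, CAF.CM and CAF.CM + antibody.

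The next comparison sets CAF.CM against control medium. Interferon-stimulated genes and most of the inflammatory list were higher with CAF.CM. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2, was 410-fold higher (log2 ratio 8.68, interval 8.57 to 8.81) and reached 1668 CPM. The chemokine gene Ccl5 was 103-fold higher (log2 ratio 6.69), and Nos2, the inducible nitric oxide synthase gene, stood at 5.49. Susd2 (6.29), Orm1 (5.41), Ms4a4c (5.31), Ptgs2 (5.28), Cfb (5.14), Ifi205 (5.05), Iigp1 (5.05) and Ly6a (5.03) were also among the highest. Cfb shared 81.5% of its 31-base words with other annotated genes, mainly an overlapping one, so its reads are uncertain.

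Of 30 measured interferon-stimulated genes 24 were higher and 0 lower, with a median of 2.15. Irf7, a transcription factor that drives type I interferon genes, was at 3.73, Rsad2 at 3.67, Oasl1 at 3.56 and Ifit2 at 3.50. Inflammatory genes were higher in 15 of 25 members (median 1.68) and lower in 3, which were Ccl9 (-3.34), Ccl3 (-1.10) and Tnf (-1.05). MHC class I genes were higher in 5 of 16 (median 0.84), led by the peptide transporter gene Tap1 (2.11), B2m (1.75) and H2-K1 (1.58). MHC class II genes were mixed, with Ciita at -2.31, Cd74 at -1.13, H2-Oa at 2.31, H2-Ob at 2.01 and H2-Ab1 at -0.02 (interval -0.05 to 0.01), a sign that turned with other scalings. Maturation genes were higher in 9 of 21 members (median 0.98), among them Il12a (5.60), Il12b (2.60), Cd40 (1.97) and Il15ra (1.91). Cd80 was at 1.05, Cd86 at -0.10 and Cd274 at 1.79. In the JAK-STAT list 6 of 23 were higher, with Socs3 at 2.78 (interval 2.70 to 2.87), Socs1 at 2.46, Cish at 1.94 and Jak2 at 1.47, and Stat3 was at 0.16.

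Macrophage and monocyte markers were lower with CAF.CM in 10 of 18 members (median -1.64) and higher in 3, which were Ly6c2 (2.24), Cd14 (1.29) and Fcgr3 (1.17), with the chemokine receptor gene Ccr2 30.9-fold lower (log2 ratio -4.95, interval -5.08 to -4.82). The complement genes C1qb (-3.88), C1qc (-3.83) and C1qa (-3.42) lay with it. The conventional dendritic cell list was lower in 5 of 15 members and higher in 1, Ccnd2 (1.65), with a median of -0.41. Itgax, from this list, was 18.6-fold lower (log2 ratio -4.22), and Kmo was at -4.41. Among the lowest genes were Galnt9 (-5.84), Siglecf (-5.73), Mamdc2 (-5.73), Klrb1a (-5.31), Cx3cr1 (-5.06), Ccr2, Nes (-4.94), Rgs16 (-4.69), Fat3 (-4.64), Fcrls (-4.60) and Efr3b (-4.42). Matrix and adhesion genes were lower in 13 of 24 members and higher in 3, the highest at 5.69, with a median of -1.23. The lower members included the elastase gene Mmp12 (-3.55), Mmp13 (-3.29) and Mmp9 (-3.27). Genes of IL-4-driven alternative activation were lower in 9 of 18, among them Cd163 (-3.96), Matk (-3.71) and Egr2 (-3.59), and higher in 4, which were Chil3 (1.81), Ccl24 (1.49), Ccl22 (1.43) and Clec10a (1.28). The LXR and lipid list was lower in 6 of 20 members, with Apoe at -3.30 and Lpl at -2.34, and higher in 3, which were Scd1 (1.82), Scd2 (1.73) and Npc2 (1.71), and the serine synthesis gene Psat1 stood at -3.54.

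Glycolysis and hypoxia genes were higher in 9 of 28 and lower in 1, Pfkfb4 (-1.07), with a median of 0.73 and with Ero1l at 2.12 and Egln3 at 2.07. Among fibroblast markers Dcn (4.33) and Col5a1 (2.20) were higher and Postn (-2.67) lower, of 7 measured. The Wnt receptor gene Fzd1 was at -2.23 and Fzd7 at 1.04.

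Across 13329 genes 891 were higher and 1158 lower with CAF.CM, and for 640 and 758 the counting interval lay wholly beyond 2-fold. The authors' deposited table has 4349 genes with an adjusted p below 0.05, 1849 higher and 2500 lower. The control and Wnt2 libraries were several times deeper than both CAF.CM libraries, and processed pseudogenes had a median of 0.73 here against 0.08 in the Wnt2 comparison and 0.05 in the antibody comparison, so medium and library pair cannot be separated. The 9 mitochondrial transcripts examined had a median of -1.88 with CAF.CM. Among genes listed in all tables, protein-coding genes took 81.2% of reads in control medium, 80.1% with Wnt2, 75.8% with CAF.CM and 72.4% with CAF.CM + antibody, and the nuclear RNA Malat1 took 1.38%, 1.76%, 2.86% and 3.86%.

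**Figure D2:**
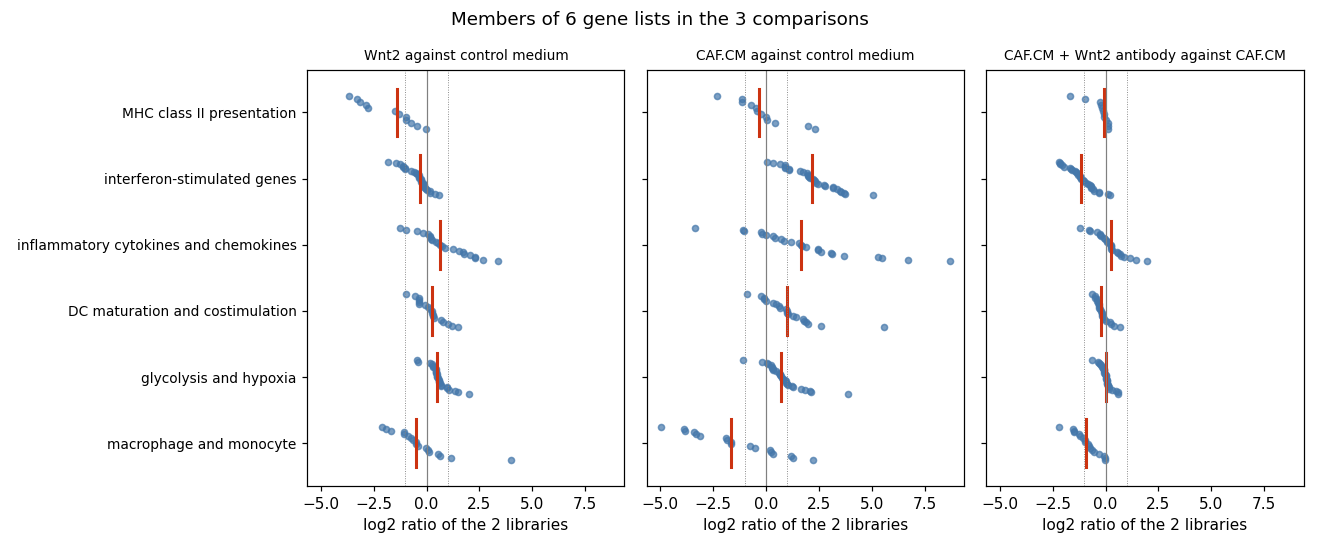
Each point is the log2 ratio of 1 gene between the 2 libraries of a comparison, for 6 gene lists, with a red line at the list median and dotted lines at 2-fold. The interferon-stimulated genes have medians of -0.32, 2.15 and -1.16 in the 3 comparisons, and the MHC class II genes -1.39, -0.33 and -0.09.

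The last comparison of single treatments asks what differs when CAF.CM is first incubated with the Wnt2 antibody. Interferon-stimulated genes were lower with the antibody than in CAF.CM alone, in 17 of 30 members with 0 higher (median -1.16). Rtp4 was 4.60-fold lower (log2 ratio -2.20, interval -2.44 to -1.99), Ifit2 was at -2.17 (interval -2.35 to -2.00), Ifi44 at -2.14 and Ifit3 at -2.06. Socs3 was 2.06-fold lower (log2 ratio -1.05, interval -1.15 to -0.94), and the interleukin-10 receptor gene Il10ra was at -1.01, with Jak2 at -0.17 and Stat3 at 0.01, which turned sign with total counts. The chemokine genes Cxcl1 (1.98, interval 1.83 to 2.15) and Cxcl2 (1.18) and the prostaglandin synthase gene Ptgs2 (1.46) were higher.

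The lowest named genes were Pagr1a (-4.17), Ifitm6 (-2.92), Ifi213 (-2.91), Siglec1 (-2.64), Tgtp2 (-2.47), Iigp1 (-2.32), Tgfbi (-2.28), Ccr2 (-2.22), Clec12a (-2.21), Rtp4, Ifit2 and Ifi44. Pagr1a shared 97.7% and Tgtp2 94.6% of their words with other genes, and Ifit3 61.8%, so reads could be split between copies and these values are uncertain. Besides Cxcl1, Ptgs2 and Cxcl2 the highest named genes were Gdf15 (1.74), Hamp (1.49), Cd24a (2.64-fold), Fam71f2 (1.35), Hist1h2bf (1.29), Serpini1 (1.23), Slco4a1 (1.18), Hist1h2ap (1.16) and Six4 (1.15). The 2 histone genes share much of their sequence with other histone genes.

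Macrophage and monocyte markers were lower in 7 of 18 with 0 higher (median -0.90), including Ccr2, Sirpb1a (-1.53), C1qc (-1.50) and C1qb (-1.47). Sirpb1a shared 48.4% of its words with other genes, so its value is uncertain. MHC class II genes had a median of -0.09, with Ciita at -1.68 and H2-Ab1 at 0.11. Maturation genes had 0 of 21 beyond 2-fold (median -0.23), with Cd86 at -0.48, Cd80 at -0.23, Cd40 at -0.10, Il12b at 0.27 and Cd274 at 0.39. Cholesterol biosynthesis genes had a median of 0.36 with 0 of 21 beyond 2-fold, and Sqle stood at 0.89. Matrix and adhesion genes were lower in 3 of 24, which were Serpinb2 (-1.40), Vcan (-1.27) and Fn1 (-1.13), with 0 higher and a median of -0.38. Inflammatory genes were higher in 3 of 25 and lower in 1, Ccl2 (-1.20). The 9 mitochondrial transcripts had a median of -1.43.

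Across 13072 genes 133 were higher and 477 lower, and for 23 and 163 the counting interval lay wholly beyond 2-fold. With at least 100 counts in 1 library these counts were 47 and 261, and among protein-coding genes 79 were higher. The authors' deposited table has 912 genes with an adjusted p below 0.05, 186 higher and 726 lower.

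Genes that differed with CAF.CM were then followed into the antibody library. Of the 12848 genes in both tables, 891 were higher with CAF.CM, and 102 of these were at least 2-fold lower with the antibody, 14 of them from the interferon list. By the rule for named genes 51 qualified, led by Ms4a4c, Ifi205, Iigp1, Ifi213, Ifit2, the guanylate-binding protein gene Gbp5 (-1.02 with the antibody), Abca13 (-1.07) and Ifit3. The median antibody ratio of all 891 was -0.07, and libraries simulated with no antibody effect gave -0.01, -0.06 and -0.16 at assumed biological coefficients of variation of 0, 0.1 and 0.2. The median was thus within the simulated range, and the number back by 2-fold, 102, exceeded the simulated 0.55, 2.5 and 36.4. Those simulations hold no general fall with the antibody. Over all 13072 genes 3.65% were lower with the antibody, and of 832 genes lower with CAF.CM 137 were lower with it too. The excess over simulation therefore does not by itself mark a return towards control.

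Of the 1158 genes lower with CAF.CM, 326 were below 1 CPM in CAF.CM and are not listed in the antibody table, so their antibody ratio is not known here. By the listing rule of about 1 CPM they would also lie below that with the antibody, unless left out for another reason. Of the other 832 genes 20.7% had an antibody ratio above 0, and 7 were higher by at least 2-fold. Their median antibody ratio was -0.41, where simulation gave 0.01, 0.07 and 0.21, and 137 of them were at least 2-fold lower again. Pde2a, a cyclic nucleotide phosphodiesterase gene, was the 1 named gene in the returning direction (-1.34 with CAF.CM, then 2.14-fold higher with the antibody), and it shared 90.9% of its words with other genes. The covariance of both ratios over genes was 0.047 against -0.013, -0.034 and -0.098 in simulation.

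**Figure D3:**
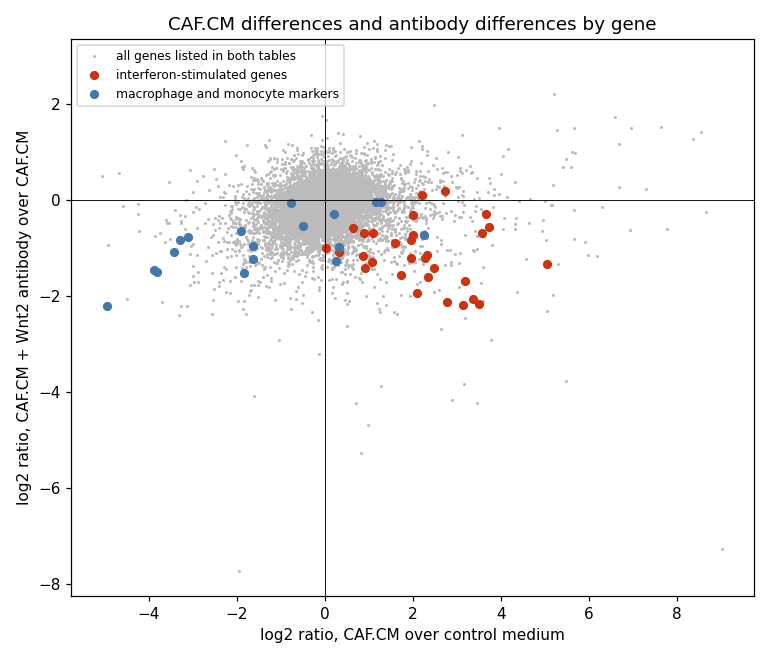
Each grey point is 1 of the 12848 genes in both tables, with its log2 ratio CAF.CM over control medium (x axis) and CAF.CM + Wnt2 antibody over CAF.CM (y axis), interferon-stimulated genes in red and macrophage and monocyte markers in blue. The red points lie mostly to the right and below 0, and the blue points below 0 with a median of -0.90.

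Wnt2 and CAF.CM differences were compared over the 12954 genes listed for both. Of these, 321 were higher and 385 lower with Wnt2, and 659 were higher and 1158 lower with CAF.CM. Of genes higher with Wnt2, 141 were also higher with CAF.CM (16.3 for independent lists), among them Ptgs2, Ddit4, Smpd5, Dgat2 and Tnfrsf9. Of genes lower, 234 were shared (34.4 for independent lists), among them Cx3cr1, Mamdc2, Cd5l, Clec12a, Lpl and Itgax. In opposite directions, 20 were higher with Wnt2 and lower with CAF.CM (28.7), and 24 the reverse (19.6). Unchanged libraries simulated against the same control shared 0, 0.1 and 21.6 higher genes and 0.05, 0.1 and 9.55 lower genes at assumed coefficients of 0, 0.1 and 0.2. Across genes, which are not replicates, Pearson's r was 0.45, and unchanged libraries simulated against the same control gave 0.28, 0.44 and 0.48 at the 3 assumed coefficients, so r does not stand apart from the shared control. The covariance was 0.211 against 0.0026, 0.023 and 0.087. Part of the overlap may come from the shared control library.

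Wnt2 and antibody ratios share no library. Over 12507 genes Pearson's r was 0.13 and Spearman's rho 0.20, both positive. Genes lower with Wnt2 had a median antibody ratio of -0.48, and 22.3% of the 292 had an antibody ratio above 0 of any size, while the 311 genes higher with Wnt2 had a median of -0.12. Clec12a, Ciita and C1qc were lower in both comparisons, Socs3, Vcan and Ifitm1 were higher with Wnt2 and lower with the antibody, and Ptgs2 and Cxcl1 were higher in both. Only genes listed for both comparisons enter here, 311 higher and 292 lower with Wnt2, and 72 higher and 426 lower with the antibody. Of genes at least 2-fold apart, 58 were lower in both (9.95 for independent lists) and 15 higher in both (1.79). In opposite directions, 29 were higher with Wnt2 and lower with the antibody (10.6), and 1 was lower with Wnt2 and higher with the antibody (1.68).

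Positions are from GENCODE M21 on GRCm38, matched by Ensembl identifier. Socs3 (ENSMUSG00000053113) lies on chromosome 11 from 117966079 to 117970047 on the minus strand, and H2-Ab1 (ENSMUSG00000073421) on chromosome 17 from 34257689 to 34269419 on the plus strand. Ciita (ENSMUSG00000022504) lies on chromosome 16 from 10480059 to 10528418, and an exon of it overlaps Dexi on the opposite strand. Ifit2 (ENSMUSG00000045932) lies on chromosome 19 from 34550694 to 34576419, and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252. All 5 are annotated as protein-coding, and the values cover the whole gene rather than single exons.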

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

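Own TMM factors and thinning of the deeper library were chosen after seeing the data, the other alternatives before. No paired analysis was possible because each group has 1 library, and no library could be left out. The alternative without a filter removes nothing and tests nothing, and TPM or FPKM was not run because the tables used here hold no such column. Of 82 values of main counts and comparisons 69 stayed within 1.5 times of the count or within the interval of the value, and 13 moved beyond it. The 69 include 6 values without a filter, and the Wnt2 counts at a minimum of 100 counts, where all 13120 genes remained. None of these could move. Of 540 list medians 511 were the same and 29 moved, and of 2170 values of named genes 2082 were the same and 88 moved. The 511 include the Wnt2 list medians at a minimum of 100 counts, which could not move either. In 7 results, all within 0.039 of 0 as reported, 10 values changed sign: H2-Ab1 with CAF.CM (0.026 with DESeq2 factors, 0.043 with total counts), the Wnt2 median of cholesterol genes, and with the antibody Stat3, Car2 and the medians of MHC class I genes, plasmacytoid markers and fibroblast markers (0.71 with members of at least 100 counts).

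The antibody counts depended on low counts. At a minimum of 100 counts, 133 higher and 477 lower became 47 and 261, and among protein-coding genes 79 were higher. That minimum kept 10361 of the 13072 genes, so the smaller number of genes alone does not account for the fall to 47 and 261. With a minimum of 100 counts the antibody median of genes higher with CAF.CM went from -0.069 to -0.033, and at a 1.5-fold threshold to -0.0073. For genes lower with CAF.CM it went from -0.41 to -0.46 with total counts and -0.28 at 1.5-fold. The correlation of Wnt2 and CAF.CM ratios went from 0.447 to 0.429 (100 counts), 0.453 (prior 5), 0.476 (protein-coding) and 0.443 (control library in 2 parts). That of Wnt2 and antibody ratios went from 0.135 to 0.145 (prior 5) and 0.199 (Spearman). The cause of these shifts was not tested. No scaling moved the median of all genes by more than 0.061. Thinning the deeper library gave 894 higher and 1137 lower genes for CAF.CM, against 891 and 1158, so depth alone changed little there.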

Other observations

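The tests of counting error, of Wnt2 acting alone, of cell shares, of the shared library, of a stronger medium, of RNA quality, of GC content and length and of the library pairs were chosen only after the results were seen. The tests of depth and of shared sequence were written before their results. Neutrophil markers were higher with Wnt2 (4 of 5, median 2.63-fold) and lower with CAF.CM (2 of 4, median -1.06), with Mmp8 at 1.45 and -1.96. Of the 16 neutrophil markers, 11 were listed in no table, S100a9, Ly6g, Elane and Mpo included, so the few measured genes do not show a share of neutrophils. Platelet markers had medians of 0.19 and -1.24, with Ppbp at 0.56 and -4.25 and Vwf (-1.04) the 1 of 6 beyond 2-fold with Wnt2. Mitotic genes had medians of -0.36, 0.76 and 0.38 in the Wnt2, CAF.CM and antibody comparisons, but the members beyond 2-fold were all higher, 2 of 15, 5 of 16 and 2 of 15. With Wnt2 these were Mki67 (1.31) and Bub1 (1.08), and Mki67 stood at -0.73 with the antibody. DNA replication genes had medians of -0.16, 0.02 and 0.10. Lysosome genes had medians of -0.24, -0.32 and -0.06, oxidative phosphorylation genes -0.26, 0.01 and 0.04, and NRF2 genes -0.18, -0.07 and 0.21, with Osgin1 (1.52) the 1 of 17 beyond 2-fold with Wnt2. Immediate early genes stood at 0.06, -0.27 and -0.33, with Egr1 at -1.30 with the antibody. Pattern recognition receptors stood at 0.02, -0.16 and -0.33, and Tlr2 at 1.43 with Wnt2 and -1.02 with CAF.CM. Tolerogenic genes had medians of 0.21, -0.28 and -0.12, with Arg1 at 0.90, -1.32 and -0.64.

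Wnt receptors had medians of 0.05, -0.37 and 0.04, LXR and lipid genes -0.16, -0.46 and -0.30, and plasmacytoid markers -0.05, 0.09 and -0.03. Mast cell markers stood at -0.66, -2.11 and -0.75, and T and NK cell markers at -0.46, -0.73 and -0.19. Of these lists 9 of 14 and 8 of 15 genes were listed in no table, and with the antibody only 3 and 4 were measured. The medians thus do not show a share of these cells. Markers of other types rested on 1 or 2 measured genes, namely Cd22 (-0.60, -2.06, -0.48), Car2 (0.20, -0.88, 0.01), Cdh1 (0.63, -0.78, -0.20), Siglecf (-2.72 and -5.73) and, for endothelium, Kdr (1.18, 1.41, -0.09) and Pecam1. The IL-4 list was lower in 6 of 18 members with Wnt2 (median -0.26) and in 2 of 16 with the antibody, Matk (-2.13) and Fn1 (-1.13), with 0 higher in both. The integrated stress list with CAF.CM was lower in 6 of 20 and higher in 1, Ddit4 (4.01), with a median of -0.61. Fibroblast markers had medians of 0.45, 0.20 and -0.04.

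Interferon-stimulated genes were lower with the antibody. Counting error is argued against, since 28 of 30 members had an interval wholly below 0. Wnt2 raising these genes by itself is argued against. The 15 that were lower with the antibody and listed for Wnt2 had a Wnt2 median of -0.49 (counting interval -0.69 to -0.37). Fewer macrophage-like cells stay open. The 18 markers had a median of -0.90, with quartiles of -1.26 and -0.57. A lower share alone would lower them alike only where the other cells did not express them. That was not measured, so the spread of the markers does not decide the question. A test on Lyz2, Cd68, Csf1r and Apoe, picked after their values were seen, gave -0.59 and was replaced by the full list.

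Processed pseudogenes and Rn7s1 against Rn7s2 differed between the deep and the shallow libraries, with an Rn7s1 to Rn7s2 ratio of 0.62 and 0.65 in control and Wnt2 and 0.039 and 0.045 in both CAF.CM libraries. Depth is argued against, since the pseudogene median stayed at 0.67 after thinning the control, from 0.73. Over all genes with shared sequence, the excess spread in CAF.CM was 0.90 times that of the antibody comparison (bootstrap interval over genes 0.77 to 1.08). It was 1.31 times that of the Wnt2 comparison (bootstrap interval over genes 1.13 to 1.57), which leaves this open. The bound set beforehand asked for a low value against either comparison, and by it this was first read as speaking against the explanation. A low value against both was required only after the values were seen, because the 2 disagree. Among the pseudogenes themselves the 109 sharing at least 50% of their words had a median of 1.04 and the other 55 had 0.12. The difference was 0.91 (bootstrap interval over genes 0.51 to 1.49), so different assignment of near-identical reads is a candidate explanation for that part. A response to CAF.CM cannot be told apart from the library pair, because 0 libraries were shallow without CAF.CM or deep with it.

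Genes lower with CAF.CM had mostly negative antibody ratios. Chance values of the shared CAF.CM library are argued against, since they would give a median above 0 and it was -0.41 (counting interval -0.43 to -0.39). A trend with GC content or length is argued against. The antibody ratio had a Spearman rho of -0.022 with GC content and -0.0014 with length. The genes lower with CAF.CM lay -0.38 (bootstrap interval over genes -0.42 to -0.35) from other genes of like GC content and length. A correction for the trend, written before its result and later replaced by that comparison, was small (SD over genes 0.039) and decides nothing. Fewer macrophage-like cells (marker median -0.90, with unlike members) and a stronger action of the medium (median -0.059 over 867 genes higher with CAF.CM, 44.5% of them with an antibody ratio above 0) could not be decided. For these 2, the bound was made stricter after a first result was seen, which had favoured fewer macrophage-like cells on the 4 picked genes (-0.59) and spoken against a stronger medium. Poorer RNA, or fewer cytoplasmic transcripts, stays open. The 9 mitochondrial transcripts, all protein-coding, had medians of -1.88 and then -1.43, though not all were beyond 2-fold. Malat1 had ratios of 0.99 and 0.46, both short of 2-fold. Mitochondrial ribosomal RNA did not fall, with 2.58% of reads in control medium, 3.12% with CAF.CM and 3.43% with CAF.CM + antibody. Its level may also depend on the depletion of ribosomal RNA. A fall of the antibody ratio with transcript length, which was also asked for, was not seen (rho -0.0014). For the step before it, CAF.CM over control medium, the rho with length was -0.103, and for Wnt2 over control medium it was 0.117. No value of RNA integrity is given in the sources used here. An action of the antibody is untested, as no library with antibody and no CAF.CM was analysed here.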
